A study of Mus musculus with 18 samples.

How the data were processed

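RNA was sequenced from the skin and the lung of female wild-type mice in 3 groups of 3 mice per tissue, which gives 18 libraries. Per the labels' protocols, AD mice were treated for 28 days with 4 nmol calcipotriol (MC903, a vitamin D analogue) and 50 µg ovalbumin, La-Cer mice with the same agents and a linoleic acid-ceramide emollient, and control mice were untreated. RNA was taken with a Promega Eastep kit, and libraries were made from 1.5 µg of total RNA with a SMARTER mRNA-Seq kit. The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.9.1 and the genome build GRCm38. The aligner, the counting tool and the strandedness are not given in the sources used here, so reads of overlapping, antisense and near-identical genes could not be told apart.

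The authors' table for each tissue holds raw read counts per Ensembl gene for 9 libraries, per the file headers and the whole-number values. The same tables hold FPKM by the authors, per the file headers. All 498609 FPKM values per tissue equal the count divided by the exonic gene size and the column total to within 0.0051, so the FPKM add no second measurement and were not tested. The tables list 55401 genes, of which 55141 were found in GENCODE vM21 and 54821 of these have the same chromosome, start and end there. Exonic sizes and coordinates are those of the tables, transcript GC content is from GENCODE vM21, and 107 symbols stand for more than 1 gene. Symbols of the fixed lists that the tables lack were looked up among the synonyms of a gene reference table.

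Columns were matched to groups through the library codes in the labels, and each tissue was fitted on its own. Counts were tested with edgeR 4.0.16 in R 4.3.3. The settings were TMM scaling, filterByExpr on the groups, and the quasi-likelihood fit and test with robust estimation over the 9 libraries of the tissue, which share one estimate of the spread. P-values are adjusted by the Benjamini-Hochberg method over all genes tested in that comparison, and a gene is called changed at an adjusted p under 0.05. Each tissue has 3 comparisons: AD against control, La-Cer against AD and La-Cer against control. The difference of the AD effect between skin and lung was tested as an interaction term over all 18 libraries. The file headers use 2 of the control codes and all 3 La-Cer codes in both tissues, so these skin and lung libraries may share mice, while the AD codes differ in their letters; the test has no term for the mouse and treats all libraries as independent. Levels are TMM-scaled CPM as mean ± SD over 3 libraries, and log2 fold changes are given ± SE.

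A floor of 3 counts over a group of 3 libraries stands for a group in which all libraries are at 0. Where a group holds 1 to 3 counts, the ratio of the counts is given with its exact 95% interval. No molecular identifiers are named, so these intervals and floors cover counting error only.

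Lists of genes for 17 processes and 21 cell types were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The p-values are adjusted over all lists of the tissue and comparison, and lists with fewer than 3 tested members were not tested. A list's count adjusted over the list alone is given beside the count over all genes. The processes are the vitamin D response, type 2 inflammation, epithelial alarmins and the interleukin 1 family, interleukin 17 and neutrophil recruitment, interferon and the type 1 response, the cornified envelope, stress keratins, ceramide and barrier lipid synthesis, cholesterol synthesis, PPAR targets and fatty acid oxidation, oxygenation of linoleic and arachidonic acid, tight junctions, itch signalling, the extracellular matrix, cell division, airway mucus, and antibody class switching and immunoglobulin. The cell types are T and innate lymphoid cells, B cells, macrophages, dendritic cells, neutrophils, eosinophils, mast cells and basophils, adipocytes, skeletal muscle, hair follicle, sebaceous gland, melanocytes, cartilage, endothelium, red blood cells, alveolar type 1 and type 2 cells, club cells, ciliated cells, cardiac muscle and thymus.

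The comparisons, tests, lists and alternatives, and the rule for the genes named in the text, were fixed before the data were examined. For each comparison the rule takes the 5 largest rises and the 5 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted and clone names. It adds up to 3 called members of each list with the smallest p, or 2 members by level where none passed, 10 genes per tissue that are always reported, and every called gene where 5 or fewer passed. Genes named outside the rule are marked as chosen after their values were seen. Non-overlap of 3 against 3 libraries occurs by chance for 10% of genes.

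The alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, only the 6 libraries compared, the replicate number as a block, a fold threshold of 1.5, library weights, each library left out in turn, and, for lists, an estimated correlation and fry. Same-numbered libraries of lung control and La-Cer deviate together (correlations of 0.31, 0.13 and 0.19 after removal of the group means), so for that comparison values with the block stand beside the result; the labels do not say what the numbers mark. After the data were seen, the removal of a trend with exonic size and GC content was added. It uses natural splines with 4 degrees of freedom per property, fitted to each library's deviation from the gene means. Leaving out each library in the interaction test, 5 further gene lists, given as levels with no list test, and a camera test of GO terms with 10 to 300 genes (952 in skin, 978 in lung) were also added then. The genes changed by AD that moved back with La-Cer were set beside 20 simulations in which La-Cer libraries were drawn with the AD means, because both comparisons share the AD libraries. After the data were seen, these values were also computed with the AD libraries split 1 against 2 between the comparisons and with the trend removed.

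The steps were tested on simulated counts drawn with the real means, spreads and library sizes for the AD against control comparison of each tissue. In the first version, 100 genes were changed 2-fold and 100 genes 4-fold. The skin test over 16956 genes recovered 0 and 0 of them, with median absolute log2 changes of 1.15 and 2.08 and the right sign for 97% and 100%. The lung test over 17272 genes recovered 4 and 52. Since a step that recovers nothing could not be checked, a wider version with 50 genes each at 2-, 4-, 8- and 16-fold was then added. It recovered 1, 19, 41 and 45 genes in skin and 2, 36, 42 and 47 in lung, with 5 calls among the unchanged genes in each tissue. A small set of 2- or 4-fold changes would therefore mostly be missed in skin at this replicate number. With a trend like that of the real libraries added and then removed, the wider version recovered 2, 15, 37 and 47 genes in skin over 16526 genes, and 6, 32, 43 and 48 in lung over 16997 genes. Camera recovered a planted 2-fold list of 20 genes in both tissues and called 0 of 50 unchanged lists. The simulated genes were drawn independently of one another. This step therefore does not show how often camera calls unchanged lists of correlated genes in the real data.

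Library totals ran from 13472283 to 19338972 counts. Between replicates of a group, the chi-square per degree of freedom of the counts against counting error alone ran from 5.91 to 276, so the spread between mice and libraries, and not depth, sets the precision of most values. All counts belong to gene lines, and 0 columns belong to samples outside the series. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.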

Results

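Transcripts were counted in skin and lung of control mice, of mice given calcipotriol and ovalbumin (AD), and of AD mice that also received a linoleic acid-ceramide emollient (La-Cer), with 3 mice per group. Skin libraries held 18647521, 15012196 and 18587243 counts in control, 17957440, 15221992 and 15269480 in AD, and 13472283, 18304788 and 17939498 in La-Cer. Lung libraries held 18532389, 17492702 and 16614340 in control, 17107391, 15904723 and 17052859 in AD, and 19139144, 19338972 and 18821411 in La-Cer. The first principal component held 37.8% of the variance in skin and 45.2% in lung. The libraries also differed by transcript length. In skin, genes in the longest of 5 classes of exonic size stood 0.62 ± 0.28 log2 units above the shortest class in control, -0.67 ± 0.40 in AD and 0.04 ± 0.40 in La-Cer (SD, n = 3). In lung the values were -0.25 ± 0.88, 0.56 ± 0.22 and -0.33 ± 0.16, and control replicate 1 stood at -1.27. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows, for AD against control in both tissues and for La-Cer against AD in lung. It was 0.2 for La-Cer against AD in skin. Because length moves with the groups, values with this trend removed are given where they end or add a call, and for AD skin, where they end all calls, together after the counts.

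**Figure D1:**
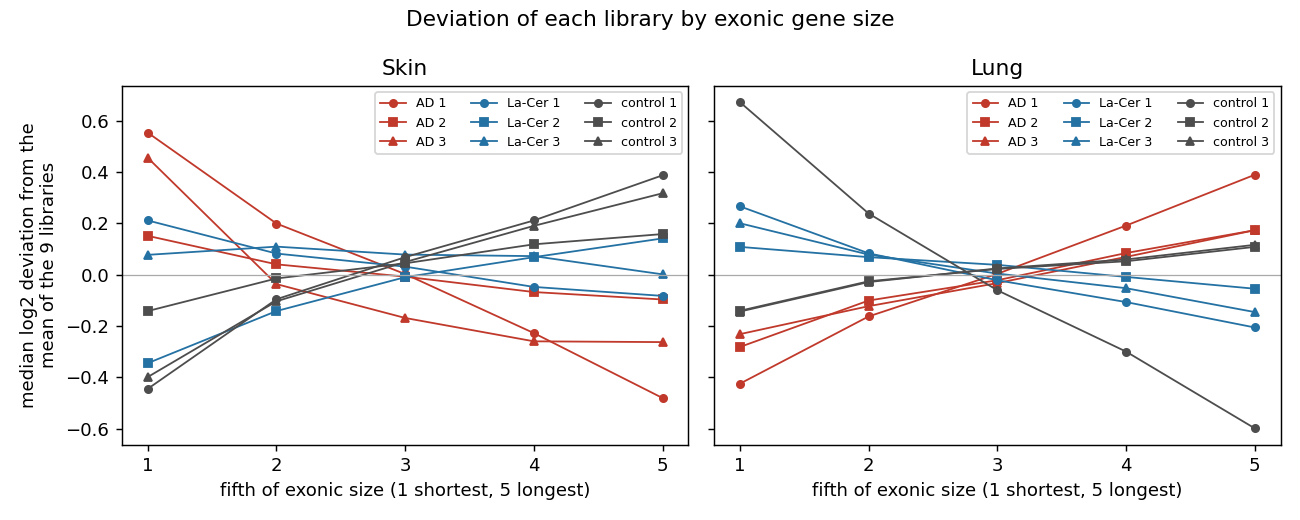
Median log2 deviation of each library from the mean of the 9 libraries of its tissue (vertical axis) by 5 classes of exonic gene size, shortest to longest (horizontal axis), for genes with a mean of at least 50 counts. Each line is 1 library. AD skin falls towards long genes (-0.67 ± 0.40 from shortest to longest class) and control skin rises (0.62 ± 0.28), while AD lung rises (0.56 ± 0.22).

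The first comparison asks what the treatment changed in the skin. Genes of stressed and hyperproliferative epidermis rose in AD skin. Krt16 (ENSMUSG00000053797, GRCm38 chromosome 11, 100246091 to 100248902), a keratin of wounded and thickened epidermis, rose from 41 ± 24.4 CPM in control to 829 ± 594 in AD (SD, n = 3; log2 4.34 ± 0.96, edgeR quasi-likelihood adjusted p = 0.0421). Sprr2a1 and Sprr2d, small proline-rich proteins that are cross-linked into the cornified envelope, rose by log2 6.88 ± 1.51 and 5.80 ± 1.17. Sprr2b had 387 counts in AD against 3 in control (ratio 164, 95% interval 55.8 to 800). The serine protease inhibitor Serpinb3a had 207 against 1 (ratio 264, 46.8 to 10500). Sprr2 and Serpinb3 genes have near-identical neighbours, so the share of reads of each single copy is uncertain. Of 23 tested genes of the stress keratin list, 7 rose over all genes tested and 15 adjusted over the list alone. Its median log2 change was 2.37 (camera adjusted p = 9.6e-07; adjusted p = 0.4 with an estimated correlation). Rptn (ENSMUSG00000041984, chromosome 3, 93393699 to 93399442), a granular layer protein bound into the envelope, rose from 13.6 ± 5.88 to 345 ± 192 CPM (log2 4.66 ± 0.76). Its relative Hrnr rose by 2.80 ± 0.71. The cornified envelope list had 2 of 37 genes up (3 adjusted over the list alone) and a median of 0.68 (camera adjusted p = 0.012; adjusted p = 0.57 with an estimated correlation, and 0.06 with the length and GC trend removed). Flg, the filaggrin gene, stood at 165 ± 79.5 against 23 ± 17.5 CPM (edgeR adjusted p = 0.0668). Lor, the loricrin gene, stood at 500 ± 406 against 1130 ± 1370 (edgeR adjusted p = 0.4), and neither passed. Control replicate 3 alone held Lor at 2710 CPM, with 220 and 456 in control replicates 1 and 2 and 956, 371 and 175 in AD. The lipid enzymes Elovl3 (598 ± 348 against 47.2 ± 12.6 CPM), Elovl7 and Degs1, which lengthen fatty acids and desaturate ceramide precursors, rose by log2 3.66 ± 0.76, 2.48 ± 0.49 and 2.47 ± 0.54.

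Inflammatory transcripts rose with them. The alarmin pair S100a9 and S100a8, which neutrophils and stressed keratinocytes make, rose from 2.58 ± 1.83 to 181 ± 227 CPM (log2 6.14 ± 1.24) and from 8.07 ± 4.81 to 169 ± 167 CPM (4.39 ± 1.03). The antimicrobial peptide gene Defb14 rose by 3.58 ± 0.79. Of 12 tested genes of interleukin 17 signalling and neutrophil recruitment, 6 rose (9 adjusted over the list alone; median 3.58, camera adjusted p = 1.2e-05, adjusted p = 0.4 with an estimated correlation). Il1f6, the gene of the cytokine interleukin 36 alpha, rose from 0.166 ± 0.194 to 9.52 ± 1.61 CPM (5.80 ± 0.94). Il1b rose by 5.66 ± 1.41 and Il1f5, the gene of the interleukin 36 receptor antagonist, from 23.6 ± 19.6 to 87.9 ± 15.7 CPM. Their list had 3 of 12 genes up (4 over the list alone; median 1.09, camera adjusted p = 0.0033, adjusted p = 0.4 with an estimated correlation). Among type 2 genes Il13ra2, a decoy receptor for interleukin 13, rose from 0.794 ± 0.323 to 21.1 ± 11.6 CPM (4.72 ± 0.90) and Chil3 by 5.05 ± 1.16. The type 2 list had 2 of 19 genes up, also over the list alone (median 0.81, camera adjusted p = 0.0031, adjusted p = 0.4 with an estimated correlation). Il4 (log2 0.81 ± 0.71), Il33 (-0.35 ± 0.78) and Tslp (0.32 ± 0.96) did not pass, with edgeR adjusted p from 0.476 to 0.849. Control replicate 3 set the control level of Tslp and Il33. Tslp stood at 0.467, 0.678 and 9.74 CPM in control replicates 1, 2 and 3, and at 4.1, 4.3 and 5.2 in AD. Il33 stood at 7.14, 14.8 and 69.3 in control and at 24.1, 31.8 and 15.5 in AD. Il13 was too low to test. The mast cell protease Cma1 (ENSMUSG00000022225, chromosome 14, 55941451 to 55944675) rose from 1.16 ± 0.317 to 19.6 ± 10.3 CPM (4.07 ± 0.61). The tryptase gene Tpsb2 rose from 1.35 ± 0.371 to 6.14 ± 2.35 CPM, and Hdc, which makes histamine, by log2 3.59 ± 0.87.

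Markers of other immune cells rose too. The mast cell list had 5 of 9 genes up (7 over the list alone; median 2.19, camera adjusted p = 5.4e-05), and neutrophils 3 of 5 (5 over the list alone; 4.39, which stays the median with Mpo at its floor, 0.0025). T and innate lymphoid cells had 4 of 14 (6; 1.96, 0.00073), macrophages 1 of 15 (3; 1.01, 0.0039) and dendritic cells 1 of 14 (4; 0.88, 0.0065). With an estimated correlation the adjusted p of each of these 5 lists was 0.4. The neutrophil list shares S100a8 and S100a9 with the neutrophil recruitment list above, so the rises of these lists are not separate evidence. Stressed keratinocytes also make both transcripts, and the neutrophil median of 4.39 is the change of S100a8. Besides them only Mpo passed over all genes, while Cxcr2 and Csf3r passed over the list alone. The T cell receptor constant genes Trbc1 and Trbc2 rose by log2 2.71 ± 0.65 and 1.83 ± 0.43, and Cd5 by 2.21 ± 0.48. The lipopolysaccharide co-receptor Cd14 rose by 3.20 ± 0.67 and the co-stimulatory molecule Cd86 by 3.04 ± 0.70. The myeloperoxidase gene Mpo had 53 counts in AD and 0 in control (at least 22.5-fold higher, with 3 counts over the control group as the floor). Blk, the 1 tested B cell marker, had 90 and 0 (at least 38.2-fold higher). Of 2 tested eosinophil markers, Ear2 (log2 -1.10, edgeR adjusted p = 0.578) and Alox15 (1.95, adjusted p = 0.135), neither passed. Mx1, an interferon-induced gene, rose by 2.89 ± 0.73, while its list did not pass (1 of 15 genes up, also over the list alone; median 0.48, camera adjusted p = 0.13).

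Lipid, matrix and gland genes also rose. The ceramide and barrier lipid list had 5 of 35 genes up and 2 down (12 and 2 over the list alone; median 0.40, camera adjusted p = 0.004, adjusted p = 0.4 with an estimated correlation). Pmvk of the cholesterol pathway rose by log2 1.33 ± 0.34, the only gene of 23 to pass (0 over the list alone; median 0.82, camera adjusted p = 0.0039, adjusted p = 0.57 with an estimated correlation). Ltc4s, the leukotriene C4 synthase, rose by 2.12 ± 0.54. The list for oxygenation of linoleic and arachidonic acid had 1 of 23 genes up (3 up and 1 down over the list alone; median 0.75, camera adjusted p = 0.035, 0.4 with an estimated correlation and 0.054 with the trend removed). The lipid droplet protein Plin2 rose from 94.4 ± 3.75 to 450 ± 48.4 CPM (2.25 ± 0.55) while its PPAR list did not pass (1 of 26 up; median 0.50, camera adjusted p = 0.052). Lum, Mmp3 and Mmp12 of the extracellular matrix rose by 2.21 ± 0.50, 2.20 ± 0.55 and 4.48 ± 1.10. Their list had 4 of 26 up (the same number over the list alone; median 0.48, camera adjusted p = 0.046, adjusted p = 0.54 with an estimated correlation). The sebaceous markers Awat2 and Cidea rose by 3.02 ± 0.73 and 3.09 ± 0.72 (2 of 13, 5 over the list alone; median 1.42, camera adjusted p = 0.00048, adjusted p = 0.4 with an estimated correlation). Lgals7, a galectin of stratified epithelia, reached 13800 ± 1040 against 2990 ± 1040 CPM (2.21 ± 0.52) and the protease Klk8 rose by 2.91 ± 0.75. Both stand in the itch list, in which 2 of 16 rose (4 up and 2 down over the list alone). Its median was -0.08, its mean 0.23 and its camera adjusted p 0.37.

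The vitamin D receptor Vdr fell from 181 ± 54.6 to 70 ± 12.2 CPM (log2 -1.37 ± 0.31). Cyp24a1, the calcipotriol-induced 24-hydroxylase, stood at 76.5 ± 70.2 against 11.3 ± 17.4 (2.75 ± 1.38, edgeR adjusted p = 0.215) and did not pass. It stood at 0.187, 2.46 and 31.4 CPM in control replicates 1, 2 and 3, and at 16.3, 154 and 59.6 in AD, so only control replicate 3 overlapped the AD range. The vitamin D list (1 of 4 down; median -0.87, camera adjusted p = 0.37) did not pass. Among genes within the naming rule, which leaves out rare transcripts and predicted names, the largest falls were in Cntn2, a neural adhesion molecule (-4.17 ± 1.08), Prkcz2 (-3.87 ± 0.98) and Cacna1i, a calcium channel (-3.86 ± 0.99). They were followed by the histone methyltransferase Kmt2d (13.5 ± 11.4 against 192 ± 48.3 CPM, -3.83 ± 0.72) and Dnajb13 (-3.56 ± 0.72). Cgn, the tight junction protein cingulin, fell by 2.50 on the log2 scale, Lep, the leptin gene, by 2.03 and the cartilage collagen Col11a2 by 3.00. The lists for tight junctions (1 of 19 down; median -0.50, camera adjusted p = 0.22), adipocytes (1 of 12 up, 1 down; 0.45, 0.37), cartilage (1 of 5 down, 2 over the list alone; -2.38, 0.13) and melanocytes (0 of 8; -1.78, 0.15) did not pass. Nor did those for hair follicle (0 of 19; -1.16, 0.37), endothelium (0 of 14; 0.41, 0.65), skeletal muscle (0 of 15; 0.30, 0.55), cell division (0 of 24; -0.22, 0.95) and antibody genes (0 of 4; 0.01, 0.68). The haemoglobin gene Hbb-bs rose by 2.03 ± 0.47 (red blood cell list 1 of 7 up; 0.64, 0.14). Tissue content varied between skin samples: the summed muscle list ran from 3810 to 65100 CPM and the hair follicle list from 339 to 33500 CPM, within and across groups.

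In all, edgeR's quasi-likelihood test called 580 genes higher and 583 lower among 16956, with 4895 at an unadjusted p under 0.05, where 848 would be expected by chance. The median log2 change was 1.89 for risen and -1.62 for fallen genes. Among the 51 called genes named by the fixed rule, Il1b overlaps between AD and control libraries. All calls lie between adjusted p 0.0413 and 0.05. The number falls to 0 with a fold threshold of 1.5 and with the length and GC trend removed, where the smallest adjusted p is 0.0739. Of the 51 named genes 0 pass with the trend removed, at adjusted p from 0.0739 to 0.158, and all 51 keep their sign. Krt16 then stands at log2 4.14, S100a9 at 4.81, Cma1 at 3.34, Rptn at 4.52, Kmt2d at -2.75, Vdr at -0.98 and Trbc2 at 1.10. The nuclear transcripts Malat1 (40.7, 112 and 89.3 CPM in AD against 384, 359 and 461 in control) and Xist (74.6, 146 and 188 against 620, 542 and 737) moved with the group as well. Risen genes had a median exonic size of 1728 bases, fallen genes 7786 and tested genes 3863. The number was 0 without control replicate 1, control replicate 2, AD replicate 1 or AD replicate 2, 2 without AD replicate 3 and 535 without control replicate 3. It was 496 with only the 6 libraries compared, 1908 without the filter, 2879 with DESeq2 and 3746 with library weights.

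**Figure D2:**
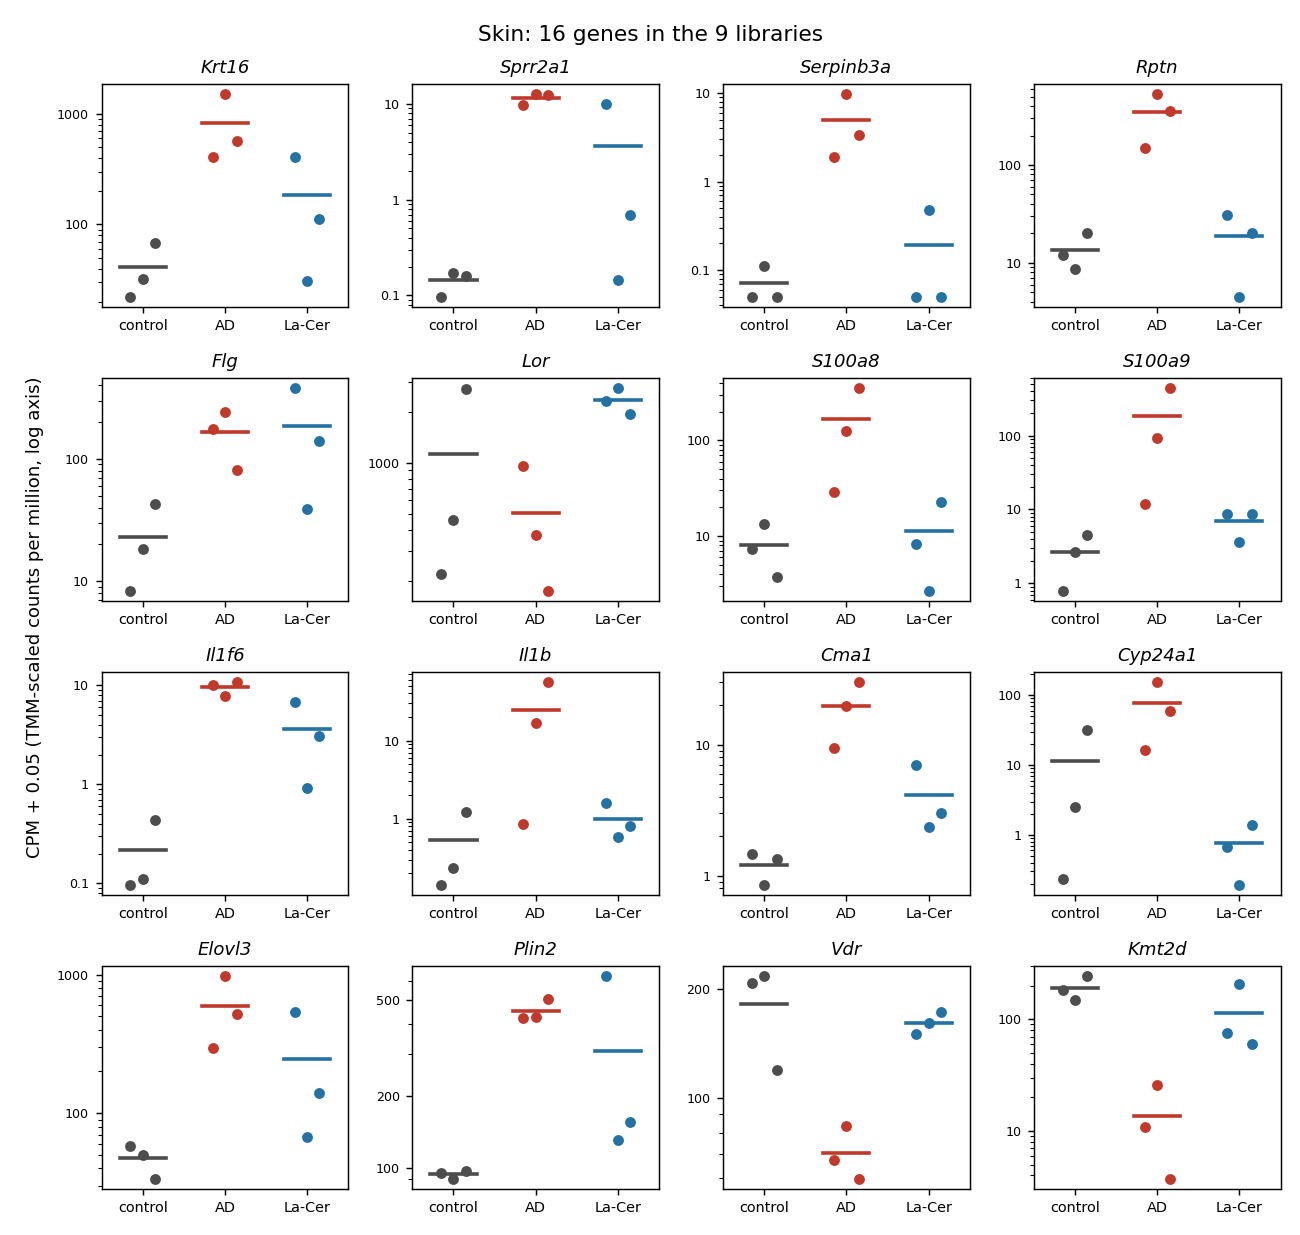
TMM-scaled CPM plus 0.05 on a log axis (vertical) for 16 genes in the 9 skin libraries, by group (horizontal). Each dot is 1 library and each line the mean of 3; Krt16 averages 41 CPM in control, 829 in AD and 185 in La-Cer, and Vdr 181, 70 and 161.

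The second comparison asks what the emollient changed in AD skin. No single gene passed the test, and some lists of inflammatory genes were lower in La-Cer than in AD skin while others did not pass. S100a9 stood at log2 -4.69 ± 1.15 and S100a8 at -3.92 ± 1.01 relative to AD (edgeR adjusted p = 0.143 for both). Cyp24a1 stood at 0.704 ± 0.606 against 76.5 ± 70.2 CPM (-6.76 ± 1.71, adjusted p = 0.143 by edgeR) and Vdr at 161 ± 10.9 against 70 ± 12.2 (1.20 ± 0.31, 0.143). Cma1 stood at 4.06 ± 2.49 against 19.6 ± 10.3 (-2.28 ± 0.56, 0.141) and Krt16 at 185 ± 200 against 829 ± 594 (-2.17 ± 0.87, 0.232). The loricrin gene Lor stood at 2330 ± 405 against 500 ± 406 (2.22 ± 0.90, 0.232). Alox12e, an epidermal lipoxygenase, stood at 512 ± 289 against 168 ± 11.8 (1.60 ± 0.46, 0.152), and Flg at 186 ± 175 against 165 ± 79.5 (0.17 ± 0.79, 0.922). As lists, interleukin 17 and neutrophil recruitment fell (0 of 12 genes, 9 over the list alone; median -3.56, camera adjusted p = 8.4e-06), as did mast cells (0 of 9, 7 over the list alone; -1.41, 2.7e-05), and stress keratins (0 of 23, 1 over the list alone; -1.05, 0.00018). Also lower were macrophages (0 of 15, 2 over the list alone; -0.98, 0.00089), neutrophils (0 of 5, 3 over the list alone; -3.09, 0.034), extracellular matrix (0 of 26, 3 over the list alone; -0.59, 0.0058), endothelium (-0.65, 0.0094) and skeletal muscle (-1.73, 0.00017), while tight junctions rose (0.65, 0.021). With an estimated correlation their adjusted p was 0.51 to 0.57, and with the length and GC trend removed a fall of adipocytes also passed (0.019). The neutrophil and interleukin 17 lists share S100a8 and S100a9 here too, so their falls are not separate evidence. The lists for type 2 inflammation (-0.15, 0.18), alarmins (-0.74, 0.13), T cells (0.04, 0.97), dendritic cells (-0.20, 0.66) and interferon (0.21, 0.66) did not pass, nor did the cornified envelope (0.33, 0.14) or ceramide and barrier lipids (0.12, 0.85). The 3 type 2 markers always reported, Il4 (log2 -1.05), Il33 (0.22) and Tslp (-1.32), did not pass.

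The edgeR test called 0 of 16956 genes, with 3198 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0585. DESeq2 called 910, edgeR without the filter 449, library weights 0, only the 6 libraries compared 1, and the fit without AD replicate 3 called 1.

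La-Cer skin was also set against untreated control. Epidermal and T cell genes were higher as lists, and no single gene passed. Flg stood at 186 ± 175 against 23 ± 17.5 CPM (log2 3.01 ± 0.85), Alox12e at 512 ± 289 against 106 ± 53.4 (2.27 ± 0.47), Klk8 at 2.63 ± 0.74, Plin2 at 1.70 ± 0.54 and Cyp24a1 at -4.00 ± 1.54, all with an edgeR adjusted p of 0.836. The T cell list rose (0 of 14 genes, 7 over the list alone; median 1.75, camera adjusted p = 2.4e-09), as did the cornified envelope (0 of 37, 0 over the list alone; 0.89, 4.7e-11). So did ceramide and barrier lipids (0.62, 1.1e-06), stress keratins (1.15, 2.2e-05), cholesterol synthesis (0.61, 2.3e-05) and sebaceous gland (0 of 13, 4 over the list alone; 1.11, 0.00015). Further lists that rose were dendritic cells (0 of 14, 3 over the list alone; 1.43, 0.00018), alarmins (0.68, 0.00048), oxygenation of linoleic and arachidonic acid (0.33, 0.00048), the interferon response (0.65, 5e-04), type 2 inflammation (0.61, 0.001) and neutrophils (1.44, 0.034). Skeletal muscle (-1.44, 6.5e-06) and endothelium (-0.31, 0.0069) fell. With an estimated correlation the adjusted p of these 14 lists was 0.31 to 0.43, and with the length and GC trend removed neutrophils did not pass (0.057) and a fall of adipocytes did (0.047). The edgeR test called 0 of 16956 genes, with 968 at an unadjusted p under 0.05 and a smallest adjusted p of 0.836. DESeq2 called 60 and edgeR without the filter 7.

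Of the 1163 genes changed by AD in skin, 0 passed the edgeR test in La-Cer against AD, with or without a change of direction. DESeq2 gave 692 that moved back. In sign, 99.4% moved opposite to the AD change, against 66.8% in 20 simulations with no La-Cer effect (64.5 to 69), in which the shared AD libraries alone act. The median gene moved back by 69.4% of its AD change (simulated 11, 9.88 to 12.3), and 934 genes lay nearer to control than to AD. Across all genes the covariance of the 2 log2 changes was -0.929 (simulated -0.217) and their correlation -0.797 (simulated -0.242). Genes are not independent replicates. With the 3 AD libraries split 1 against 2 between the differences of mean log2 CPM, the covariance ran from -0.467 to -0.691 over 6 splits, against -0.773 unsplit. No AD library stands on both sides of a split, so the covariance left there does not come from shared AD libraries. Over the 6 splits 97.1 to 99.4% of the 1163 genes moved opposite in sign. Their median return ran from 47.7 to 102%, so it depends on which AD library is used. These genes were called with all 3 AD libraries, so part of their excess in sign and return may still come from that choice. On average the length trend moved back too, from 0.62 in control and -0.67 in AD to 0.04 in La-Cer. So did Malat1 (259, 275 and 91.6 CPM in La-Cer) and Xist (286, 523 and 166). La-Cer replicate 3 lay within the AD range of both transcripts (40.7 to 112 and 74.6 to 188 CPM). The length trend also overlapped between the groups (-0.29 in La-Cer replicate 1, -0.25 in AD replicate 2). With the trend removed 1134 of the 1163 genes moved opposite in sign (1156 with it), by a median of 70.1% and with a covariance of -0.78. The simulations hold no such trend, draw each gene independently and called more AD genes (2720 on average) than the data. Cyp24a1, which calcipotriol induces, stood at 0.621, 0.144 and 1.35 CPM in La-Cer against 16.3, 154 and 59.6 in AD. La-Cer and AD skin also differ in how FPKM of 0 are written, as described below. The return therefore cannot be assigned to the emollient alone.

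The same treatment was applied to the skin, and the lung comparison asks whether the airways changed. In AD lung Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), the inducible cyclooxygenase, rose from 11.9 ± 2.21 CPM in control to 43.3 ± 6.99 (log2 1.86 ± 0.21, edgeR quasi-likelihood adjusted p = 0.0313). The ribosomal protein gene Rps16 (ENSMUSG00000037563, chromosome 7, 28350652 to 28353155) fell from 234 ± 162 to 16.9 ± 3.57 (-3.79 ± 0.46, 0.0313). H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), a major histocompatibility class II chain of antigen-presenting cells, fell from 65.3 ± 15.4 to 12.5 ± 4.09 (-2.38 ± 0.29). Uridine phosphorylase Upp1 fell from 35.8 ± 8.32 to 10.1 ± 0.204 (-1.83 ± 0.21), the depalmitoylase Abhd17a from 101 ± 9.37 to 39 ± 3.64 (-1.37 ± 0.17) and Fam167b from 3.84 ± 0.961 to 0.56 ± 0.12 (-2.76 ± 0.34). The 2 other called genes, Gm8210 (-3.13 ± 0.38) and Gm3756 (-2.25 ± 0.22), are predicted names outside the rule, named after their values were seen. Rps16 and processed pseudogenes share reads with near-identical copies, so their levels are uncertain.

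Neutrophil markers rose as a list in AD lung (0 of 12 genes, 8 over the list alone; median log2 1.99, camera adjusted p = 2.2e-05), as did interleukin 17 and neutrophil recruitment (0 of 11, 3 over the list alone; 1.18, 0.017). So did alarmins (0 of 10, 1 over the list alone; 0.37, 0.029), macrophages (0.42, 0.03), cell division (0.45, 0.019) and T cells (0 of 20, 6 over the list alone; 0.18, 0.049). Dendritic cells fell (1 of 15 genes, 4 over the list alone; -0.51, 0.0029), and with them PPAR targets (-0.42, 0.041) and club cells (-0.50, 0.041). With an estimated correlation the adjusted p of these 9 lists was 0.3 to 0.75, and with the length and GC trend removed club cells did not pass (0.17), while the interferon response (0.015), endothelium (0.017) and alveolar type 2 cells (0.031) did. Markers of tissues next to the lung moved with the group as well: adipocytes (-1.86, 0.00043), skeletal muscle (0 of 15, 1 over the list alone; -1.82, 0.00059), cardiac muscle (-0.79, 0.0029) and red blood cells (0 of 7, 6 over the list alone; -3.22, 0.0032) were lower, with adjusted p = 0.64 to 0.68 under an estimated correlation. Summed cardiac muscle markers overlapped between the groups (144, 1240 and 3010 CPM in AD against 2900, 1960 and 3050 in control). Those of red blood cells did too (440, 62.4 and 65.5 CPM against 4160, 124 and 1020). Chil3, a type 2 macrophage gene, stood at 376 ± 248 against 68.1 ± 14.6 CPM (2.46 ± 0.54, edgeR adjusted p = 0.084) and did not pass. Nor did Il4, Il33, Muc5ac, Clca1, Retnla, Scgb1a1, Sftpc or Ccl17, at log2 0.56, 0.34, -1.23, 0.33, -0.01, -0.43, -0.55 and 0.16 (edgeR adjusted p from 0.311 to 0.988). Cyp24a1 and Il13 were too low to test. The lists for type 2 inflammation (median 0.12, camera adjusted p = 0.36), airway mucus (-0.11, 0.26), interferon (1.33, 0.081), vitamin D (0.93, 0.21) and antibody genes (-0.82, 0.07) did not pass. The same holds for endothelium (-0.43, 0.05), cholesterol synthesis (0.11, 0.98), oxygenation of linoleic and arachidonic acid (0.12, 0.98), tight junctions (0.02, 0.98), extracellular matrix (-0.08, 0.93), B cells (-0.02, 0.85), eosinophils (0.25, 0.87) and mast cells (0.18, 0.23). It also holds for cartilage (0.34, 0.55), alveolar type 1 (-0.15, 0.55) and type 2 cells (0.25, 0.27), ciliated cells (-0.13, 0.9) and thymus (-0.01, 0.74).

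The edgeR test called 1 gene higher and 7 lower among 17272, with 3607 at an unadjusted p under 0.05, where 864 would be expected by chance. Malat1 (616, 724 and 962 CPM in AD against 41.8, 446 and 578 in control) and Xist (378, 503 and 640 against 54, 248 and 281) separated the groups as well. Control replicate 1 stood apart, and without it 994 genes were called. Without control replicate 2 the number was 12, without control replicate 3, AD replicate 1 or AD replicate 2 it was 0, and without AD replicate 3 it was 3. It was 0 with only the 6 libraries compared or a fold threshold of 1.5, 20 with RLE factors, 63 with the trend removed (all 8 genes among them), 134 without the filter, 1206 with DESeq2 and 2088 with library weights.

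The next comparison asks what the emollient changed in AD lung. Of the inflammatory and immune genes named here, only Ptgs2 and H2-Ab1 had also passed in AD against control. In La-Cer against AD lung the neutrophil chemokine Cxcl2 fell from 3.1 ± 0.596 to 0.366 ± 0.134 CPM (log2 -3.06 ± 0.45, edgeR quasi-likelihood adjusted p = 0.0313), the cytokine Il6 from 1.45 ± 0.758 to 0.0871 ± 0.0295 (-3.95 ± 0.80, 0.0463), and Ptgs2 to 12.1 ± 1.21 (-1.84 ± 0.21, 0.0137). The chemokine receptor Cxcr2 fell from 21.9 ± 10.8 to 5 ± 0.805 (-2.13 ± 0.40), the neutrophil collagenase Mmp8 by log2 3.85 ± 0.78 and Slfn4 from 65.7 ± 60.7 to 3.9 ± 0.905 (-4.07 ± 0.75). The neutrophil granule gene Ngp fell by 2.44 ± 0.51, the inhibitory receptor Lilrb4a by 2.83 ± 0.48, the collagenase Mmp13 by 2.13 ± 0.40 and Ms4a2, a chain of the mast cell IgE receptor, by 3.12 ± 0.61. Higher in La-Cer were the immunoglobulin heavy chain Ighm (163 ± 40.5 against 52.4 ± 14.7, 1.63 ± 0.33), H2-Ab1 (34.1 ± 1.83 against 12.5 ± 4.09, 1.44 ± 0.28) and the claudin Cldn3 (245 ± 26.2 against 112 ± 12.5, 1.13 ± 0.21, adjusted p = 0.042 by edgeR). Cldn3 stands at 0.52 with the trend removed and no longer passes (adjusted p = 0.185). With the trend removed Slfn4 (-3.78, adjusted p = 0.0571), Mmp8 (-3.80, 0.0818), Ms4a2 (-2.62, 0.0908), Lilrb4a (-2.41, 0.0765), Il6 (-3.48, 0.077), Mmp13 (-1.89, 0.108), Cxcr2 (-2.11, 0.0743) and Ngp (-2.84, 0.0736) miss the threshold too. So do Ighm (1.29, 0.0622) and H2-Ab1 (1.06, 0.0896), while Cxcl2 and Ptgs2 pass. Within the naming rule the largest rises were in genes for secreted odorant-binding and lipocalin proteins of nasal and other glands. Bpifb9b (ENSMUSG00000067996, chromosome 2, 154307227 to 154320646) had 573 counts in La-Cer and 0 in AD (at least 173-fold higher), and Obp1b 389 and 0 (at least 117-fold). Mup4 had 254 and 0 (at least 76.7-fold), Bpifb9a 205 and 0 (at least 61.9-fold) and Obp2a 314 and 1 (ratio 284, 50.7 to 11300). The skeletal muscle genes Acta1 (82.5 ± 66.6 against 1.22 ± 0.528, 6.07 ± 1.02) and Atp2a1 (3.02 ± 0.60) rose as well, and miss the threshold with the trend removed (5.51, adjusted p = 0.0537, and 2.78, 0.077).

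Neutrophil markers fell as a list in La-Cer lung against AD (3 of 12 genes, 9 over the list alone; median log2 -1.55, camera adjusted p = 0.0012), as did interleukin 17 and neutrophil recruitment (2 of 11, 3 over the list alone; -1.11, 0.0048). The same held for macrophages (0 of 16, 3 over the list alone; -0.61, 0.0048), alarmins (-0.64, 0.0076), the interferon response (-1.44, 0.011) and cell division (-0.44, 0.033). Airway mucus genes rose (0 of 17; 0.98, 0.0048), with ciliated cells (0.86, 0.0048), and club cells (0.82, 0.0048). Further rises were those of antibody genes (1 of 11, 2 over the list alone; 0.94, 0.011), tight junctions (1 of 20, 3 over the list alone; 0.26, 0.041) and dendritic cells (1 of 15, 4 over the list alone; 0.43, 0.041). With an estimated correlation the adjusted p of these 12 lists was 0.38 to 0.86. With the trend removed antibody genes (0.056), tight junctions (0.13) and dendritic cells (0.13) did not pass. Skeletal muscle (2 of 15, 14 over the list alone; 3.30, 7.1e-08), cardiac muscle (1.06, 0.0048) and red blood cells (2.41, 0.0048) were higher in the same libraries, with adjusted p = 0.4 to 0.69 under an estimated correlation. Muc5ac, a gel-forming mucin, stood at 2.05 ± 0.584 against 0.589 ± 0.529 CPM (1.78 ± 0.65, edgeR adjusted p = 0.133), Scgb1a1 at 0.77 (0.313), Clca1 at 1.42 (0.352) and Chil3 at -2.35 ± 0.53 (0.0555), and none of these 4 passed.

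The edgeR test called 146 genes higher and 184 lower among 17272, with 4397 at an unadjusted p under 0.05. The median change was log2 1.51 and -1.19, and the median exonic size 1657 and 6930 bases against 3916 for tested genes. The number was 12 without AD replicate 1, 16 without AD replicate 3, 1 without La-Cer replicate 2, and 0 without AD replicate 2, La-Cer replicate 1 or La-Cer replicate 3. With the trend removed it was 76 (47 higher, 29 lower), of which 45 were shared, and 11 of the 330 genes changed sign. Without the filter it was 413, with 251 higher and 162 lower. Malat1 (134, 218 and 252 CPM in La-Cer against 616, 724 and 962 in AD) and Xist (135, 165 and 208 against 378, 503 and 640) moved with the group as well. With a fold threshold of 1.5 it was 14, with DESeq2 2179, with only the 6 libraries compared 4011 and with library weights 5948.

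**Figure D3:**
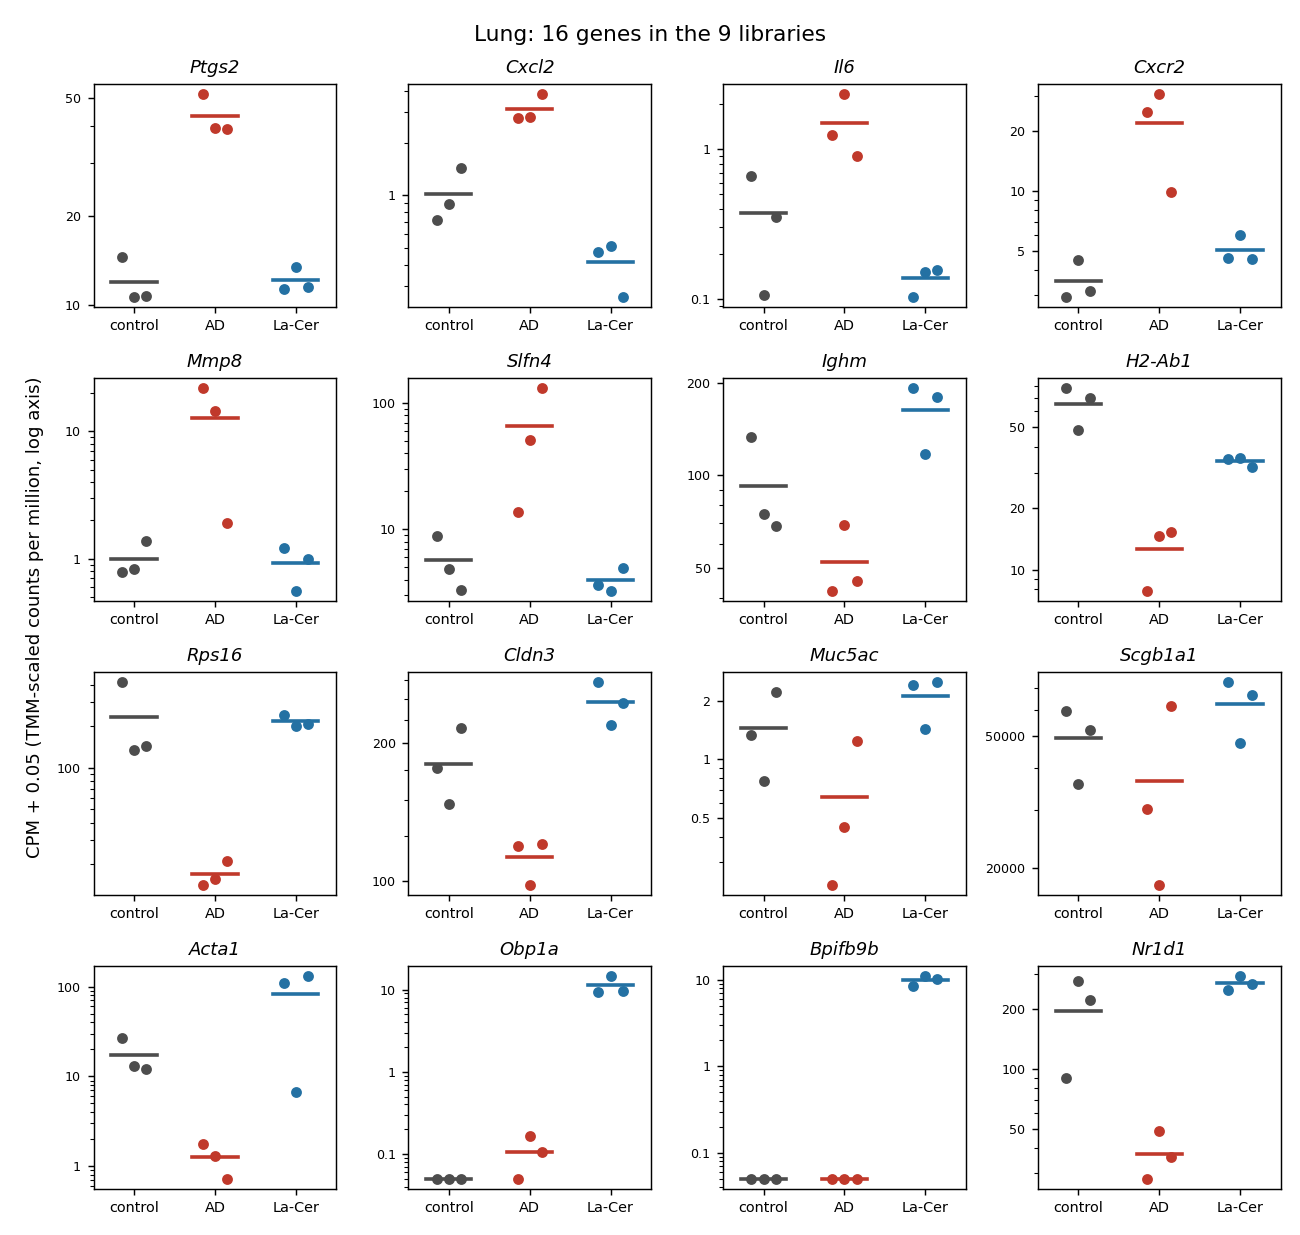
TMM-scaled CPM plus 0.05 on a log axis (vertical) for 16 genes in the 9 lung libraries, by group (horizontal). Each dot is 1 library and each line the mean of 3; Ptgs2 averages 11.9 CPM in control, 43.3 in AD and 12.1 in La-Cer, and H2-Ab1 65.3, 12.5 and 34.1.

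Against untreated control, La-Cer lung differed in 6 genes without a replicate block, all higher and all of the odorant-binding kind. Obp1a (ENSMUSG00000067684, chromosome X, 78085505 to 78091374) stood at 11.2 ± 2.98 CPM and at 0 in control (at least 190-fold higher, edgeR adjusted p = 0.0149), Bpifb9b was at least 169-fold and Obp1b at least 115-fold higher. Gm14743, a predicted neighbour named after its values were seen, was at least 204-fold higher. Obp2b (3.97 ± 0.967 CPM) had a ratio of 202 (35.9 to 8000) and Obp2a (5.47 ± 1.22 CPM) of 139 (38.1 to 1150). As lists, skeletal muscle (0 of 15, 4 over the list alone; median log2 1.74, camera adjusted p = 2.1e-06), ciliated cells (0.62, 4.6e-07), and tight junctions (0.34, 0.00042) were higher. So were airway mucus (0.55, 0.0012), B cells (0.33, 0.0014), vitamin D (0.44, 0.038), cholesterol synthesis (0.16, 0.044), T cells (0.17, 0.044) and alveolar type 2 cells (0.13, 0.044). Adipocytes (-1.41, 6.7e-05), PPAR targets (-0.52, 0.0023), endothelium (-0.36, 0.013) and dendritic cells (-0.32, 0.044) were lower. With an estimated correlation the adjusted p of these 13 lists was 0.2 to 0.65. The edgeR test had 548 genes at an unadjusted p under 0.05, fewer than the 864 expected by chance. Without control replicate 1, which stood apart, it had 3879, so the low number depends on that library. The 6 calls became 21 without control replicate 1, 2 without control replicate 3, and 0 without control replicate 2 or any 1 La-Cer replicate. With the replicate number as a block, 0 genes are called, with or without the trend (Obp1a at edgeR adjusted p = 0.141). The block is given here because same-numbered libraries deviate together in this comparison alone, a choice made from these data. In skin the same-numbered control and La-Cer libraries correlated at -0.32, -0.46 and -0.73. The labels do not say what the numbers mark, so the block may pair unrelated mice. Under the block the lists for cholesterol synthesis (0.068), T cells (0.052) and dendritic cells (0.05) no longer pass, while alveolar type 1 cells (0.048) and club cells (0.029) rise. The calls became 0 with only the 6 libraries compared, 11 without the filter, 20 with DESeq2 and 5229 with library weights.

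All 8 genes that AD changed in lung passed in the opposite direction in La-Cer against AD, 1 that AD raised and 7 that it lowered. Independent lists would share 0.01 and 0.06, but both comparisons use the same AD libraries, so these values are no fair reference. The simulations with no La-Cer effect gave 0. They called 0.05 genes on average in La-Cer against AD, where the data gave 330, so their 0 was nearly fixed in advance. Neither reference shows that the 8 exceed what shared AD libraries give. The median return of the 8 genes was 96.3% of the AD change (simulated 13.9, 12.6 to 15.1). None of them passed the edgeR test in La-Cer lung against control, where H2-Ab1 stood at log2 -0.94, Upp1 at -0.85 and Rps16 at -0.10. From AD to La-Cer H2-Ab1 regained 1.44 of its fall of 2.38 and Upp1 0.98 of 1.83. A full return to control is therefore not shown for these genes. Across all genes the covariance of the 2 log2 changes was -0.523 (simulated -0.106) and their correlation -0.811 (simulated -0.264). The simulations called far more AD genes (1520 on average, 1410 to 1630) than the data, so their return is that of another and larger set. With the 3 AD libraries split 1 against 2, the covariance of the differences of mean log2 CPM ran from -0.268 to -0.373, against -0.427 unsplit. No AD library stands on both sides of a split, so the covariance left there does not come from shared AD libraries. In every split all 8 genes moved opposite in sign, with a median return from 87.4 to 104%. They were called with all 3 AD libraries, so part of their excess may still come from that choice. Once the trend is removed, the median return of the 8 genes was 81.3% and the covariance -0.416. The number was 779 without control replicate 1, 4 without control replicate 2, 3 without AD replicate 3 and 0 without any other 1 library. It was 29 with the trend removed, 0 with a fold threshold of 1.5 and 859 with DESeq2.

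The AD effect was then compared between the tissues. In skin against lung it was more positive for the mast cell protease Cma1 (difference of the log2 changes 5.14 ± 0.85, edgeR interaction adjusted p = 0.00687), for Lgals7 (4.11 ± 0.73), for the class II chain H2-Ab1 (3.11 ± 0.54) and for Rps16 (5.19 ± 0.57, 0.00113). It was more negative for the vitamin D receptor Vdr (-2.65 ± 0.42) and for Dnajb13 (-4.32 ± 0.78). The interaction test called 2819 of 19129 genes, 1805 more positive and 1014 more negative in skin, with 6204 at an unadjusted p under 0.05. It treats skin and lung libraries as independent, although some may share a mouse. The number was 1036 without skin control replicate 1, 1365 without lung control replicate 1, and 1347, 1859 and 1678 without lung AD replicates 1, 2 and 3. Genes more positive in skin had a median exonic size of 1990 bases, more negative ones 7167 and tested genes 3675. From control to AD the mean length trend went from 0.62 to -0.67 in skin and from -0.25 to 0.56 in lung. The interaction carries both shifts. With the length and GC trend removed 2317 genes were called.

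**Figure D4:**
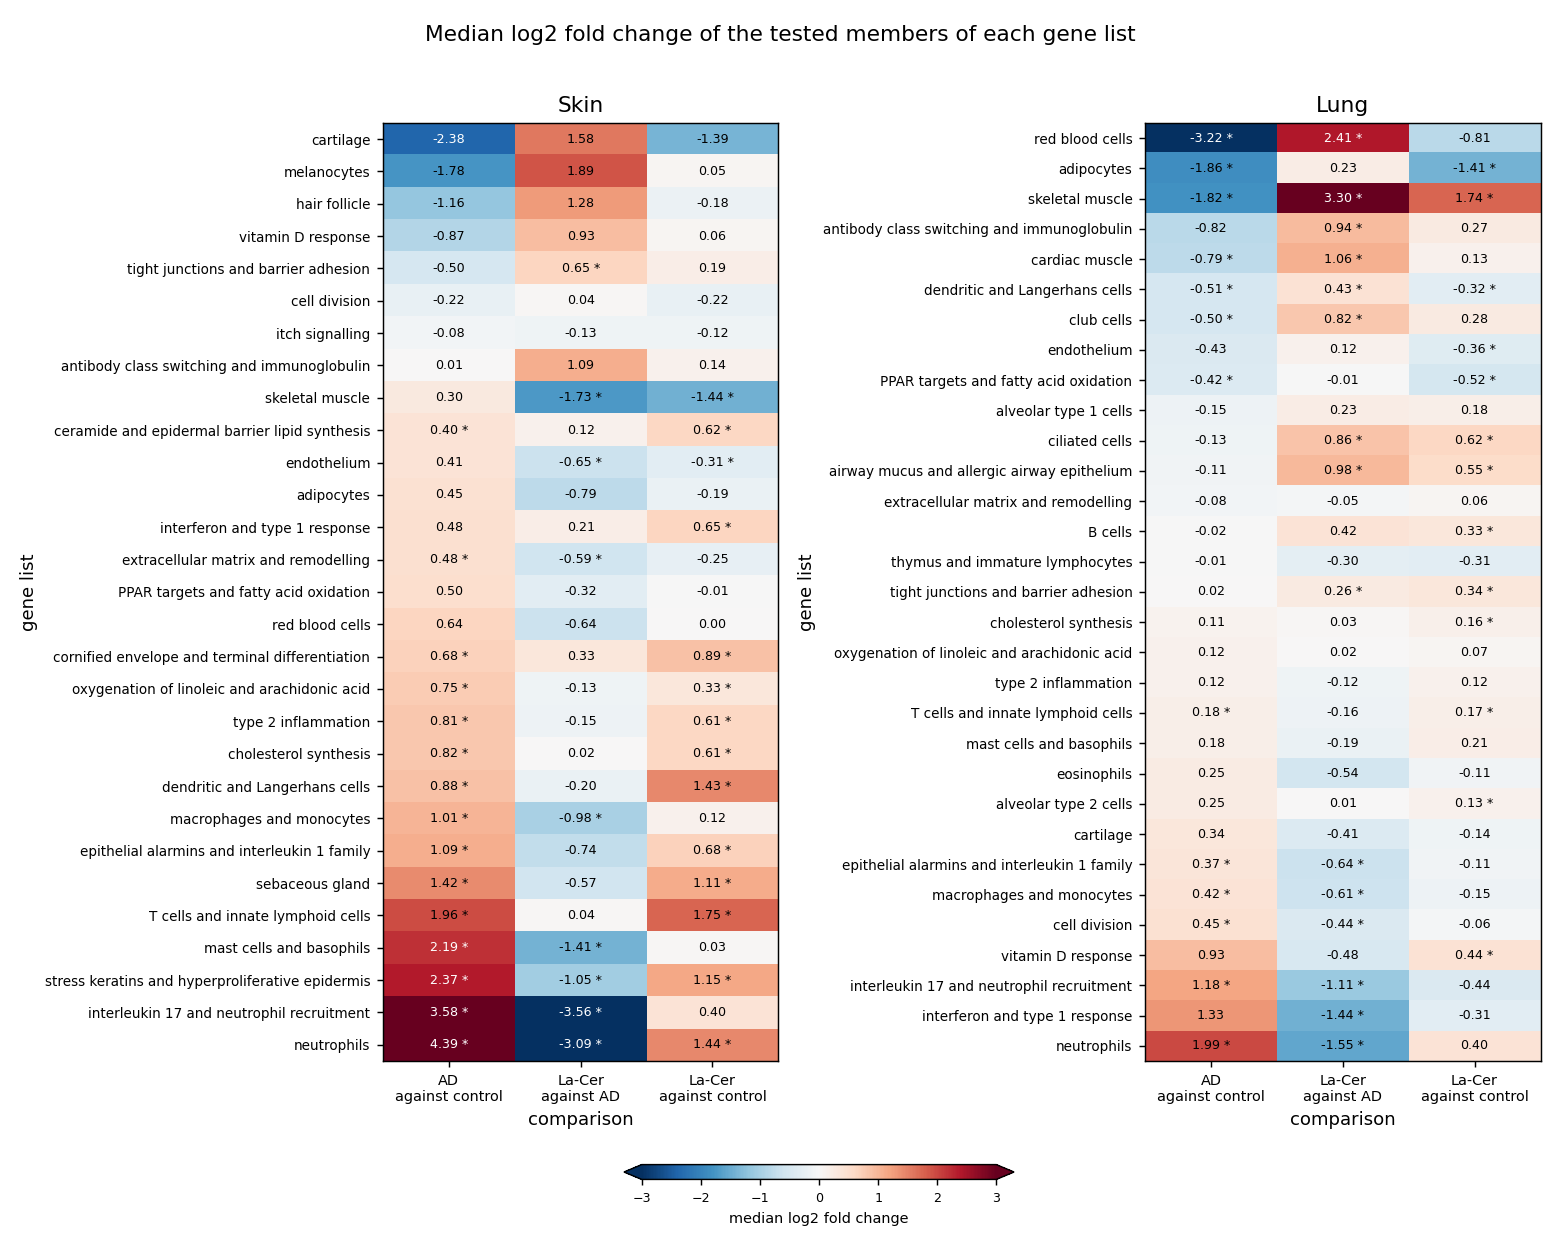
Median log2 fold change of the tested members of each gene list (rows of squares) in the 3 comparisons of each tissue (columns of squares); colour runs from blue (lower) to red (higher) and * marks a camera adjusted p under 0.05 at the preset correlation. Neutrophil markers stand at 4.39 in AD against control skin and -3.09 in La-Cer against AD skin, and at 1.99 and -1.55 in lung. In skin they include S100a8 and S100a9, which stressed keratinocytes also make.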

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

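The tests of the length trend in skin and for Rps16, of carry-over from skin and of muscle tissue, and the trend removal in the interaction, were chosen after the results were seen; the other tests below were written down before.

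A different AD effect in skin and lung brought 2819 genes here, by the interaction test. With the length and GC trend removed within each tissue the number was 2317, of which 1778 were shared with the same sign, and 5 of the 2819 changed sign. Among epidermal and lipid genes, the difference of the log2 AD changes (skin minus lung) was 7.65 for Wfdc12, 4.11 for Lgals7, 4.08 for Klk8, 4.07 for Rptn, 5.03 for Cidea, 3.41 for Awat2, 2.57 for Degs1, 2.51 for Plin2, 2.24 for Elovl7, 1.74 for Pmvk and 2.81 for Ltc4s. Among immune genes it was 8.39 for Blk, 8.11 for Mpo, 5.14 for Cma1, 5.04 for S100a9, 4.83 for Il1b, 4.65 for Cd79b, 3.95 for Cd86, 3.55 for Tpsb2, 3.30 for Hdc, 3.26 for Cd14, 3.11 for H2-Ab1, 3.10 for Trbc1, 2.50 for Trbc2 and 1.98 for Cd5. The values of Blk and Mpo are fitted ones with 0 counts in control skin, where the skin change is known only as at least 38.2-fold and 22.5-fold, and that of Cd79b rests on 1 count in control skin. It was 5.19 for Rps16, 1.83 for Abhd17a, 3.61 for Upp1, 2.80 for the endothelial claudin Cldn5, 3.09 for Lum, and 5.80, 4.64, 4.20 and 3.49 for the blood and muscle genes Hbb-bs, Hba-a1, Acta1 and Myl4. Negative differences were those of Cacna1i (-4.50), Kmt2d (-4.45), Dnajb13 (-4.32), Prkcz2 (-4.05), Cgn (-3.43), Col11a2 (-3.25), Vdr (-2.65) and Mki67 (-2.05). With the trend removed 35 of these 42 genes pass, and Pmvk, Il1b, Mki67, Hbb-bs, Hba-a1, Cidea and Acta1 do not.

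The first pattern weighed is the change of 1163 genes in AD skin, where risen genes are short and fallen genes long. With the length and GC trend removed, the median log2 change of the 580 risen genes went from 1.89 (MAD 0.73, median SE 0.43) to 1.49 (MAD 0.78, SE 0.38), or 78.6% kept, and that of the 583 fallen genes from -1.62 (MAD 0.42, SE 0.36) to -1.12 (MAD 0.46, SE 0.31), or 68.9%. All kept their sign, and the calls ended because folds shrank more than their errors did while every p already lay close to the threshold; the lowest adjusted p became 0.0739, and 443 and 378 genes stayed under 0.1. Without AD replicate 3, the most distant library, 0.172% of the calls were left (2), but leaving out control replicate 1, control replicate 2, AD replicate 1 or AD replicate 2 leaves 0, so the loss is not particular to it. The trend, this library and an effect of calcipotriol and ovalbumin cannot be told apart as the source of the calls with 3 libraries per group, and the nuclear transcripts Malat1 (at most 112 CPM in AD, at least 359 in control) and Xist (at most 188, at least 542) also separate the groups, a sign of RNA quality or composition that was not tested further.

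The second pattern is the odorant-binding and lipocalin list, whose 15 genes sum to 65, 97.2 and 71.6 CPM in the La-Cer lungs and to at most 0.692 CPM in the other 6. Reads carried over from these skin libraries are excluded as the source, since no skin library holds more than 100 Obp1a and 3 Bpifb9b reads and each La-Cer lung holds at least 175 and 160; per Obp1a read, Bpifb9b stands at 0 in skin control replicate 3, the only skin library with 30 Obp1a reads, at 3 for 7 reads in skin La-Cer replicate 2, and at 0.762 or more in La-Cer lungs. Muscle taken along at dissection was tested first by the spread of the muscle to odorant-binding ratio among La-Cer lungs. At 4.63 it fell between the bounds of 2 and 5 and decided nothing. In a second test, chosen after that outcome, the ratio was at least 1390 in control lungs and at most 11.4 in La-Cer lungs. It was 163 and 1620 in the 2 AD lungs with any odorant-binding reads. The list was added after its genes were seen near 0 in the other lungs, so a high ratio was given wherever those lungs held muscle. Muscle markers stood at 433, 211 and 334 CPM in control and 741, 239 and 777 in La-Cer lungs. This speaks against muscle like that in the control lungs, but cannot reach tissue that only La-Cer lungs carried. Olfactory mucosa stays possible: its 13 neuron genes, of which 4 are expressed enough in lung to be tested, had a median log2 difference of 0.43 (SD 0.68), with Ric8b at 27, 26.7 and 24.3 CPM and Omp at 0.637, 0.767 and 0.901 CPM in La-Cer lungs. Of the 4, Ric8b, Adcy3 and Gnal stood at log2 -0.11, 0.06 and -0.27 in La-Cer against AD and Omp at 1.83. Against control they stood at -0.05, -0.23, 0.27 and 1.11, and none passed the edgeR test. The median rests mostly on genes with too few counts to be tested. An effect of the emollient and the other group-wide handling of these 3 mice stay open as untested.

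The third pattern is the fall of Rps16 and of the predicted genes Gm8210 and Gm3756 in AD lung. The length and GC trend is excluded as the whole cause, since Rps16 keeps 87.7% of its log2 change (-3.33 ± 0.29, adjusted p = 0.00598) once it is removed. A general fall of ribosomal protein transcripts does not reach the -1.5 written down as its bound: the median of 80 genes is -0.63 (MAD 0.63), or -0.32 with the trend removed. Reads shared with near-identical copies remain a candidate, since log2 changes of 739 ribosomal protein genes and processed pseudogenes spread more widely (MAD 0.95) than 1000 random lists of matched expression (percentile 100, median MAD 0.67), though La-Cer against control stands at percentile 99.6 too (MAD 0.46), and ribosomal protein genes alone at 91 and 5.1. A true fall of Rps16 in AD lung, with its return under La-Cer, stays open as untested.

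Other splits of each set of 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. In skin the real split gave 1163 genes for AD against control (1 of 10 splits had as many; highest other 0) and 0 for La-Cer against AD (10 of 10; highest other 0). For La-Cer against control skin it gave 0 (10 of 10), while the split that puts control replicates 1 and 2 with La-Cer replicate 3 gave 337, which points to a structure among these samples other than their groups. The hair follicle list summed to 33500 and 13900 CPM in control replicates 1 and 2 and to 32100 in La-Cer replicate 3. It summed to 609 in control replicate 3 and to 2970 and 3880 in La-Cer replicates 1 and 2. This split thus separates libraries by hair follicle content, which was not tested as its source. In lung the real splits gave 8, 330 and 6 genes for AD against control, La-Cer against AD and La-Cer against control, and 1 of 10 splits had as many in each, with a highest other of 0.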

How the results depend on the processing

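Removing the trend, the block with the trend removed, and leaving out libraries in the interaction were chosen after the data were seen. No named gene that passed changed its sign and no list passed in the opposite direction, while with the removed trend 11 of the 330 genes of La-Cer against AD lung and 5 of the 2819 of the interaction changed sign. Depth limits the genes printed with count intervals or floors. The values below are numbers of calls, in the order AD against control, La-Cer against AD and La-Cer against control, and unless stated the cause was not tested.

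Against 1163, 0 and 0 genes in skin, DESeq2 gave 2879, 910 and 60, and no filter 1908, 449 and 7. For AD against control in skin, a fold threshold of 1.5 and the removed trend gave 0 each, library weights 3746 and only the 6 libraries compared 496, which also gave 1 for La-Cer against AD. Leaving out each library gave 0 to 535, 0 to 1 and 0 genes. Against 8, 330 and 6 genes in lung, DESeq2 gave 1206, 2179 and 20, library weights 2088, 5948 and 5229, and only the 6 libraries compared 0, 4011 and 0. For AD against control in lung, RLE gave 20 and a fold threshold 0; no filter gave 134, and 11 for La-Cer against control. For La-Cer against AD in lung the fold threshold gave 14. The removed trend gave 63 (23 higher, 40 lower, against 1 and 7) and 76 (47 and 29, against 146 and 184); for the latter no filter gave 413 (251 and 162). Without AD replicate 3 the AD against control lung calls were 3 higher and 0 lower. Leaving out each lung library gave 0 to 994, 0 to 16 and 0 to 21.

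Genes changed by AD that moved back with La-Cer numbered 0 in skin, where DESeq2 gave 692 and leaving out libraries 0 to 1. In lung they numbered 8, where DESeq2 gave 859, the fold threshold 0, the removed trend 29 and leaving out libraries 0 to 779. Gene lists at adjusted p under 0.05 numbered 15, 9 and 14 in skin and 13, 15 and 13 in lung. An estimated correlation gave 0 in all 6 comparisons; fry gave 7 (5 of them among the 15), 1 and 0 in skin and 1, 4 and 0 in lung. Leaving out libraries gave 13 to 19, 6 to 12 and 13 to 18 lists in skin and 7 to 13, 11 to 16 and 7 to 12 in lung, and the removed trend 13, 10 and 14 and 15, 12 and 13. The 2819 genes of the interaction became 2803 with RLE, 4131 with DESeq2, 2317 with the removed trend and 1036 to 3278 with libraries left out.

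Replicate numbers are shared between groups. Same-numbered libraries correlated from -0.73 to 0.31 after removal of the group means, and not every sample correlates best with its own number, so the numbers were taken to pair libraries only in La-Cer against control lung, where all 3 correlations exceed 0.1. With the replicate block, genes numbered 0, 0 and 0 in skin and 0, 12 and 0 in lung, and genes that moved back in lung 0; with the block and the removed trend they were 0, 0 and 0 in skin and 13, 17 and 0 in lung. Lists under the block numbered 15, 11 and 14 in skin and 13, 14 and 12 in lung. The alternative of another pseudocount does not apply, since counts were used.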

Other observations

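The GO terms, the clock genes and the 5 added lists below, and their tests, were chosen after the data were seen.

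GO terms of energy metabolism rose in AD skin and fell in AD lung at the preset correlation; the difference between the tissues was not tested. With a correlation estimated by camera 0 terms pass in any comparison (AD against control, La-Cer against AD and La-Cer against control), and the smallest adjusted p is 0.8, 0.93 and 0.97 in skin and 0.96, 0.99 and 1 in lung, so the adjusted p of every term below is at least that. In AD skin, camera gave a rise of the electron transport chain (89 genes, median log2 0.95, adjusted p = 2.1e-10; 9.8e-07 with the length and GC trend removed), ATP synthesis coupled proton transport (1.18, 2.9e-06; 0.0093) and translation (277 genes, 0.71, 1.9e-09; 0.00072), and in La-Cer against AD skin the first 2 fell (-0.73, 1.8e-07; -1.14, 3.4e-07). With the trend removed, translational termination (0.1), initiation (0.15) and elongation (0.18) did not pass in AD skin, nor translational elongation (0.58) in AD lung. Muscle terms moved alongside: skeletal muscle contraction fell in La-Cer against AD skin (-1.78, 0.0063), and cardiac muscle contraction fell in AD lung (-0.63, 0.0086) and rose in La-Cer against AD lung (0.86, 0.018). In AD lung the tricarboxylic acid cycle (-0.71, 7e-05; 5.7e-06 with the trend removed), ATP synthesis coupled proton transport (-0.99, 0.00013), the electron transport chain (-0.73, 0.00098) and translation (-0.43, 0.0018) fell, and neutrophil chemotaxis rose (0.56, 0.0038). In La-Cer against AD lung the proton transport term (0.82, 0.0027) and the electron transport chain (0.58, 0.021) rose, while the cellular response to interferon-beta (-1.35, 0.0027) and neutrophil chemotaxis (-0.64, 0.0045) fell. La-Cer skin stood above control for leukotriene biosynthesis (0.81, 0.00012; 0.00016 with the trend removed) and cholesterol biosynthesis (0.55, 0.0019; 0.0047), and La-Cer lung for cilium assembly (60 genes, 0.25, 0.0077; 0.00018). Of 952 terms in skin 66, 33 and 24 passed in AD against control, La-Cer against AD and La-Cer against control (14, 8 and 5 with the trend removed), and of 978 in lung 28, 24 and 1 (24, 22 and 1). The share of mitochondrial counts was 5.02, 10.1 and 9.84% in control skin and 2.85, 9.96 and 2.84% in AD skin.

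Of 17 genes of the circadian clock, 3 passed in La-Cer against AD lung and 0 in the other 2 lung comparisons, with no test of the group. Nr1d1, a repressor of the clock loop, rose in La-Cer against AD from 28, 48.4 and 35.9 to 248, 293 and 268 CPM (log2 2.85 ± 0.40, edgeR adjusted p = 0.0308), while Per2 (-1.45 ± 0.29, 0.0463) and Cry1 (-1.39 ± 0.27, 0.0424) fell; Dbp stood at 1.68 ± 0.41 (0.0631) and Nr1d1 in AD against control at -2.39 ± 0.39 (0.0543). The hours of tissue collection are not given in the sources used here.

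The other added lists gave levels only. Olfactory sensory neuron genes summed to 39.3, 47.6 and 40.2 CPM in La-Cer lungs, 48.6, 45.8 and 39.6 in AD and 29.9, 52.1 and 44.7 in control. Olfactory supporting cell genes summed to 467, 239 and 460 CPM in La-Cer lungs, 25.4, 132 and 228 in AD and 491, 187 and 332 in control, most of it Cyp2a5. Salivary and lacrimal gland genes summed to 8.41, 6.21 and 8.87 CPM in La-Cer lungs, 5.14, 11.8 and 11.2 in AD and 22.8, 10.3 and 8.31 in control. In skin the odorant-binding list summed to 4.34, 8.66 and 28.8 CPM in control, 4.23, 6.18 and 69.1 in AD and 8.68, 3.39 and 9.14 in La-Cer. The value of AD replicate 3 is nearly all Wfdc18 (75.5 TMM-scaled CPM), while Obp1a, Gm14743 and Bpifb9b are at 0 there.

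Lung control replicate 1 held Xist at 54 CPM, lay at -97.3 on the first principal component against 16.5 and 17.9 for the other 2 control lungs, and held red blood cell markers at 4160 CPM, where the lungs ran from 62.4 CPM. FPKM of 0 are written as 0 for skin control and AD and for lung control, and with 2 decimals for skin La-Cer and for lung AD and La-Cer. So AD against control in skin and La-Cer against AD in lung each lie within 1 format, while the other 4 comparisons and the lung part of the interaction cross formats. Whether the formats mark separate processing or sequencing batches is not given in the sources used here; if they do, groups and batches coincide in those comparisons, and this was not tested.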
